A study of Arabidopsis thaliana with 8 samples.

How the data were processed

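Transcript levels were measured in Arabidopsis thaliana roots with 8 single-colour oligonucleotide arrays, 1 array per RNA sample. Plants were wild type or carried a mutation in URI, which encodes a basic helix-loop-helix (bHLH) transcription factor of the iron-deficiency response. Per the labels, they grew for 14 days on diluted B5 medium and then spent 3 days either with 50 µM Fe(III)-EDTA (written +Fe) or without iron and with 300 µM ferrozine, an iron chelator (written −Fe). Each of the 4 combinations of genotype and iron supply had 2 biological replicates, so the number of arrays limits the precision of every value. Roots were the only tissue named in the labels.

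The deposited values are probe-set intensities made by the authors with robust multi-array averaging (RMA), per the submitters' processing notes, which give no version in the sources used here. RMA values are usually reported as log2, but these were linear, with array medians from 119.55 to 128.29, and log2 was taken before any test. A workbook table of the same arrays differed from the series table by at most 5e-06 linear units. Its annotation was joined by probe-set identifier, because 44 lines carried another identifier than the values beside them.

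Of 22810 probe sets, 64 controls were left out and 22746 were tested. The annotation gave exactly 1 gene for 21180 of them, several genes for 1039 and none for 527. The 21180 cover 21019 genes, of which 20798 were found in the RefSeq gene table used for names. No gene was named from a probe set with several genes. The 158 genes with several single-gene probe sets were represented in the gene lists by the probe set with the highest mean over all 8 arrays, and none of them had probe sets called in opposite directions by iron deficiency in wild type.

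All 8 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3, with a mean per group and empirical Bayes moderation (lmFit and eBayes). The fit left 4 residual degrees of freedom, to which moderation added a prior of 8.32 with a prior standard deviation of 0.132. The 5 contrasts were −Fe against +Fe in wild type, the same in uri, uri against wild type under −Fe, uri against wild type under +Fe, and the difference between the genotypes' iron responses (the interaction). Tests were two-sided. Each contrast was adjusted over all tested probe sets by the method of Benjamini and Hochberg, and a probe set was called at an adjusted p under 0.05. Errors given with log2 fold changes are moderated standard errors (SE).

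Gene lists of 230 genes in total were taken from textbook knowledge. They covered iron regulators, iron uptake, coumarin synthesis and secretion, general phenylpropanoid and lignin synthesis, iron distribution, iron storage, iron-requiring enzymes, copper homeostasis, zinc homeostasis, phosphate starvation, sulfate limitation, root hair markers, endodermis and suberin markers, vascular markers, cell division markers, photosynthesis, jasmonate and wounding, salicylate defence, and heat shock. Photosynthesis genes served as markers of shoot tissue. Of the 230 genes, 210 had a single-gene probe set, 9 had only shared probe sets and 11 were not in the annotation used here. FIT, FRO2, bHLH38 and bHLH100 are among those 11. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the arrays. Both camera tests compare a list with all other genes. With an estimated correlation camera also takes its p from the 4 residual degrees of freedom of the fit. A call lost there therefore does not by itself show correlated genes. For phosphate starvation genes the estimate was −0.054, below the preset 0.01. Their camera adjusted p in wild type still rose from 0.0214 to 0.111. The rotation test fry was run beside both camera tests. Its directional p tests whether a list's genes move one way on balance and its mixed p whether they change in either direction, and neither compares the list with other genes. The count of a list's members called was also taken when adjusted over the list alone.

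The genes named in the report follow a rule. URI, FIT, IRT1, FRO2, bHLH38, bHLH39, bHLH100, bHLH101, PYE, BTS, F6'H1 and FER1 were to be named in each comparison where measured. Up to 10 called genes with the largest rise, up to 10 with the largest fall, and up to 4 members of each list with the largest change followed, and the text prints those that matter most. The contrasts, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise.

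The procedure was tested on simulated arrays with the real means and spreads, in which 200 of 22746 probe sets were changed. For iron deficiency in wild type, 48% of 1.5-fold changes, 100% of 2-fold changes and 100% of 4-fold changes were recovered, and 4%, 5.21% and 7.41% of the calls were false. For the interaction, recovery was 6%, 86.5% and 100%, and 20%, 7.49% and 7.41% of the calls were false, so in that setting most interactions of 1.5-fold were missed. In the other 3 contrasts the false share lay between 5.21% and 9.09%, above the 5% aimed for. The data hold far more calls than 200 (4637 for the interaction), which makes the adjusted p less strict. These recoveries and false shares therefore describe the simulated setting and not the data.

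The alternatives were the workbook table and quantile normalization (the workbook values are linear, so both take the same steps), centring each array on its median, leaving out the 25% dimmest probe sets, testing only single-gene probe sets, a minimum of 2-fold, an adjusted p under 0.01, a trended and robust prior, only the arrays compared, replicate number as a block, and leaving out each array in turn. Where leaving out an array left a group with 1 array, that array was assumed to vary like the other groups. An alternative that chose responsive probe sets on 1 replicate number and measured them on the other was added after seeing the data.

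The −Fe arrays carry one run of array numbers and the +Fe arrays another, so array run and iron supply cannot be told apart. The genotype contrasts lie within a run, and a run effect common to both genotypes cancels in the interaction. Array quality was described by control probe sets, medians and correlations between arrays, without a test.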

Results

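Transcripts were profiled in roots of wild-type and uri plants after 3 days with or without iron. There were 2 arrays for each of 4 groups: wild type +Fe, wild type −Fe, uri +Fe and uri −Fe. URI encodes a bHLH transcription factor that acts upstream of other iron-response regulators, and the design asks how a mutant changes the root response to iron deficiency. Linear array medians lay between 119.55 and 128.29, and replicate arrays correlated across probe sets with r between 0.994 and 0.998. The lowest replicate correlation, 0.9938, was that of the uri +Fe arrays, and uri +Fe replicate 1 correlated slightly better with a wild-type +Fe array, at 0.9945.

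URI (AT3G19860), the mutated gene, was measured first on every array. Its log2 intensity was 8.73 and 8.78 on the wild-type +Fe arrays and 7.84 and 7.64 on the uri +Fe arrays. It was 8.64 and 8.60 on the wild-type −Fe arrays and 8.52 and 8.62 on the arrays labelled uri −Fe. The uri value was thus lower under +Fe by a log2 difference of −1.02 ± 0.118 (SE, 2 arrays per group, adjusted p = 0.000752), but under −Fe the difference was −0.05 ± 0.118 with a 95% interval from −0.31 to 0.20 (adjusted p = 0.804). In uri the transcript rose under −Fe by 0.83 ± 0.118 (adjusted p = 0.00019), whereas the wild-type difference was −0.13 ± 0.118 (adjusted p = 0.633), and these responses differed by 0.97 ± 0.167 (adjusted p = 0.00151). The −Fe transcript level therefore does not check the genotype of the arrays labelled uri −Fe. Where the mutation lies relative to the probes was not given in the sources used here, so an unaltered signal does not speak for an intact protein.

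**Figure D1:**
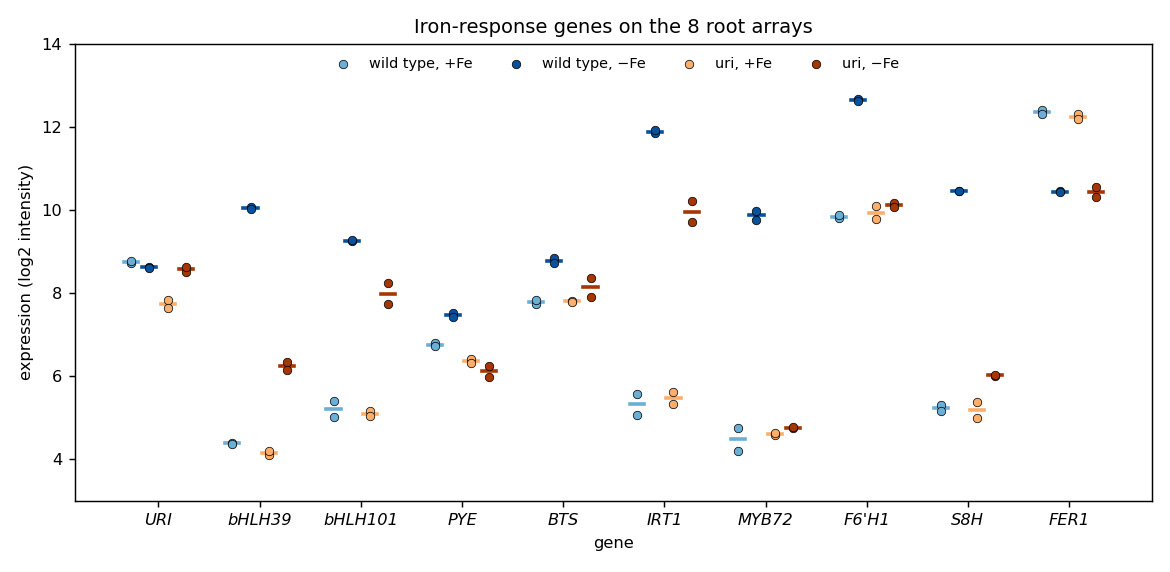
Log2 intensity of 10 iron-response genes (horizontal axis) on each of the 8 root arrays, with points for arrays and short bars for the mean of the 2 replicates per group. F6'H1, MYB72 and S8H stand far higher in wild type −Fe than in the other 3 groups, whereas FER1 is lower under −Fe in both genotypes.

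The first comparison asked what iron deficiency does to wild-type roots. IRT1 (AT4G19690), the main root iron importer, rose 94.9-fold (log2 6.57 ± 0.193 SE, 2 arrays per group, adjusted p = 7.66e-10). Among the largest rises were those of CYP82C4 (AT4G31940, log2 6.92 ± 0.186), which makes the coumarin sideretin, and of GSTL1 with a log2 change of 5.90. The regulators bHLH39 (AT3G56980) and bHLH101 (AT5G04150), partners of the master regulator FIT, rose by log2 values of 5.67 ± 0.117 and 4.05 ± 0.173. BTS (AT3G18290), an E3 ligase that restrains the iron response, rose by 1.00 ± 0.147, and F6'H1 (AT3G13610), which commits the pathway to coumarins, by 2.81 ± 0.128. PYE (AT3G47640), a bHLH repressor of iron distribution genes, rose by 0.70 ± 0.125 (adjusted p = 0.00495), a call that was lost without wild-type −Fe replicate 1 (0.66, adjusted p = 0.0785). The ferritin gene FER1 (AT5G01600), which encodes an iron store, fell 3.78-fold (log2 −1.92 ± 0.122, adjusted p = 8.94e-07). The largest fall was that of FSD1 (AT4G25100), an iron superoxide dismutase, at −2.24 ± 0.144, and the malate channel gene ALMT1 fell by 1.88.

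Every measured gene of coumarin synthesis and secretion rose in wild type (8 of 8, and 8 adjusted over the list alone), with MYB72 at a log2 change of 5.40, S8H at 5.23 and MYB10 at 3.79. Of 12 measured iron regulators 8 rose and 4 did not pass (9 rose when adjusted over the list alone). They included the iron-deficiency peptide gene IMA1 at 2.67 and BTSL1, whose 2 probe sets gave 1.98 and 2.64. Of 8 iron uptake genes 6 rose and 2 did not pass (8 adjusted over the list alone), among them the vacuolar transporter genes MTP3 at 4.06, HMA3 at 3.04 and FPN2 at 2.62. The uptake list holds these vacuolar transporters beside IRT1, so its counts in every comparison are not of iron importers alone. Iron distribution genes split into 8 that rose, 1 that fell and 9 that did not pass (8 and 2 adjusted over the list alone), with the phloem transporter gene OPT3 at 3.75, the nicotianamine synthase gene NAS1 at 2.60 and the ferric reductase gene FRO3 at 2.28. The 1 lower gene was not called without either wild-type −Fe array or wild-type +Fe replicate 1, which left 0, and 2 were called without either uri +Fe array. Of 10 iron storage genes 6 fell, 0 rose and 4 did not pass (6 fell and 1 rose adjusted over the list alone), including the vacuolar importer genes VTL2 at −1.71 and VTL1 at −1.28. General phenylpropanoid genes rose in 9 of 15 cases (9 adjusted over the list alone), with PAL2 at 1.93 and 4CL2 at 1.32, although 5 were called without wild-type −Fe replicate 2 and 6 without wild-type +Fe replicate 1. Copper homeostasis genes rose in 4 of 8 cases, led by the importer gene COPT2 at 2.77 and the copper superoxide dismutase gene CSD1 at 0.84, with 2 called without wild-type −Fe replicate 2. These 7 lists passed camera with the preset correlation (adjusted p from 2.02e-33 for coumarins to 0.000431 for copper) and with an estimated correlation (adjusted p from 0.00417 to 0.0487).

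Photosynthesis transcripts, fixed as markers of shoot tissue, fell in 16 of 22 cases in wild type and 6 did not pass (19 fell adjusted over the list alone), with PSAN at −1.24 and PSBQ2 at −1.13. The list's median was −0.76 (camera adjusted p = 2.54e-22), but adjusted p = 0.0546 with an estimated correlation. Phosphate starvation genes fell in 4 of 11 cases, including the phosphatase gene PAP17 at −1.50 and the sensor gene SPX1 at −0.99. That list's call (camera adjusted p = 0.0214) was lost with an estimated correlation (adjusted p = 0.111) and without wild-type +Fe replicate 2 (adjusted p = 0.0748), and 2 of the 4 genes were called without either wild-type −Fe array. Sulfate limitation genes passed with 2 of 10 higher, APR3 at 0.64 and APR1 at 0.61 (adjusted p = 0.00236, and adjusted p = 0.195 with an estimated correlation). The list was lost with fry (directional adjusted p = 0.0681) and without wild-type +Fe replicate 1 (camera adjusted p = 0.0576), and 0 members were called without either wild-type −Fe array or wild-type +Fe replicate 1. Heat shock genes passed with 2 of 5 lower (adjusted p = 0.0019, and adjusted p = 0.104 with an estimated correlation), but 0 were called without any 1 of the 4 wild-type arrays. The wild-type −Fe mean of the lower heat shock gene HSP17.4, 4.32, lay below the lower quartile of those arrays, 4.66. The other 8 lists did not pass camera, with adjusted p from 0.0587 for root hair markers to 0.938 for zinc homeostasis. Among them were the iron-requiring enzymes, whose median of 0.02 and mean of −0.19 differed in sign, and jasmonate genes, whose median was −0.00 and mean 0.05. For zinc genes the median of −0.05 and mean of −0.01 were below 0 while camera pointed up.

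The wild-type +Fe means of CYP82C4 (3.43), bHLH39 (4.38), MYB72 (4.48) and IMA1 (4.22) lay below the lower quartile of those arrays, 4.71. No detection call was used here, so the sizes of these 4 rises, and their rank, are uncertain.

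In wild type, limma called 1285 of 22746 probe sets, of which 798 were higher and 487 lower under −Fe. At least 2-fold changes were 192 higher and 56 lower. The count fell to 494 and 435 without wild-type −Fe replicates 1 and 2, to 647 without wild-type +Fe replicate 1, and to 821 without wild-type +Fe replicate 2. Array run and iron supply cannot be told apart in this comparison.

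The second comparison asked how uri roots respond to iron deficiency. IRT1 rose 22.3-fold (log2 4.48 ± 0.193 SE, 2 arrays per group, adjusted p = 2.19e-08), bHLH101 rose by 2.89 ± 0.173 and bHLH39 4.27-fold (adjusted p = 1.37e-07), whereas FER1 fell by 1.81 ± 0.122. F6'H1 (0.19 ± 0.128, adjusted p = 0.298), PYE (−0.25 ± 0.125, adjusted p = 0.155) and BTS (0.34 ± 0.147, adjusted p = 0.0982) did not pass. Among the largest rises were those of DIR5 (AT1G64160), a dirigent-protein gene, at 5.83 ± 0.147 and of DIN11 (AT3G49620), a dark-induced gene, at 5.46 ± 0.148. The uri +Fe means of DIR5 (3.67), DIN11 (4.32), bHLH39 (4.15), CYP82C4 (3.67), IMA1 (4.48) and the jasmonate gene JAZ8 (4.06) lay below the lower quartile of those arrays, 4.73. The sizes of their rises are therefore uncertain. Other large rises were those of SEN1, a senescence-associated and dark-induced gene, at 17.2-fold, of BCAT-2, which encodes a branched-chain amino acid aminotransferase, at a log2 change of 3.87, and of GAT1_2.1 at 3.76. The largest fall was that of the nitrate transporter gene NRT2:1 (AT1G08090) at −4.79 ± 0.144 (27.7-fold), followed by AT2G41810 at −2.89, and FSD1 fell by 2.75.

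Of 12 iron regulators 6 rose in uri, 1 fell and 5 did not pass (7 and 1 adjusted over the list alone), with IMA1 at 1.26. The 6 include URI, the mutated gene itself. The fallen regulator was not called without uri −Fe replicate 1 or uri +Fe replicate 2, which left 0. Iron uptake genes gave 5 higher, 2 lower and 1 not passed, with MTP3 at 1.95 and NRAMP1 at 1.59, and 1 of the lower genes was called without uri −Fe replicate 2 or uri +Fe replicate 1. Coumarin genes gave 4 higher, 2 lower and 2 not passed, with CYP82C4 at 4.23 and S8H at 0.84. Their list was lost without uri +Fe replicate 1 (adjusted p = 0.0508). General phenylpropanoid genes fell in 11 of 15 cases (12 adjusted over the list alone), among them 4CL3 at −1.85 and PAL1 at −0.95. Iron storage genes fell in 6 of 10 cases and rose in 1, with FER3 at −1.38. Sulfate limitation genes fell in 8 of 10 cases, including SDI1 at −2.08 and APR1 at −1.42. Cell division markers fell in 7 of 9 cases, including PCNA1 at −1.24 and MCM2 at −1.18. Root hair markers fell in 8 of 9 cases, including the cell wall gene LRX1 at −1.09, with 5 called without uri −Fe replicate 1 or uri +Fe replicate 1.

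Photosynthesis transcripts rose in 13 of 22 uri cases and 9 did not pass (14 adjusted over the list alone), with GAPA at 1.33 and LHCB4.1 at 1.17. Iron-requiring enzymes gave 2 higher and 7 lower of 15, including the nitrite reductase gene NIR1 at −1.33. Phosphate starvation genes gave 6 lower and 1 higher of 11 (0 higher without either uri −Fe array or uri +Fe replicate 1, and 2 without uri +Fe replicate 2), and jasmonate genes rose in 4 of 7 cases (2 without uri +Fe replicate 2). Camera called 12 lists with the preset correlation, namely those of the last 3 sentences and the 8 of the preceding description (adjusted p from 1.06e-07 for photosynthesis to 0.0391 for coumarins). With an estimated correlation 0 lists passed, with adjusted p = 0.146 for regulators and phenylpropanoid genes, adjusted p = 0.197 for coumarins, storage, iron-requiring enzymes, phosphate, sulfate, cell division, photosynthesis and jasmonate, adjusted p = 0.254 for uptake and adjusted p = 0.274 for root hairs. Iron distribution, with 7 higher and 5 lower of 18, did not pass (adjusted p = 0.777), and its median of −0.02 and mean of −0.01 lay below 0 while camera pointed up. Its higher count was 4 without uri −Fe replicate 2, and its lower count was 3 without either uri −Fe array or uri +Fe replicate 2.

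In uri, limma called 7528 probe sets, of which 3434 were higher and 4094 lower under −Fe, with 680 and 522 changed at least 2-fold. No left-out array moved this count by more than 1.5 times. With each array centred on its median the majority turned to higher values, at 4070 against 3338. Array run and iron supply cannot be told apart here either, and the −Fe arrays are those whose URI level does not separate them from wild type.

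The third comparison set the arrays labelled uri −Fe against wild type −Fe. MYB72 (AT1G56160), a regulator of coumarin secretion, was lower on the arrays labelled uri (log2 −5.11 ± 0.161 SE, 2 arrays per group, adjusted p = 9.89e-10). Its mean there, 4.76, lay near the lower quartile of the arrays, 4.71, so the size of this difference is uncertain. The coumarin hydroxylase gene S8H (AT3G12900) was lower by −4.43 ± 0.138, bHLH39 by −3.81 ± 0.117, F6'H1 by −2.52 ± 0.128, IRT1 by −1.93 ± 0.193 and bHLH101 by −1.28 ± 0.173. PYE was lower by −1.35 ± 0.125, and BTS by −0.64 ± 0.147 (adjusted p = 0.00594), which was lost without wild-type −Fe replicate 1 (−0.58, adjusted p = 0.0638) or uri −Fe replicate 2 (−0.41, adjusted p = 0.0827). FER1 gave a difference of 0.00 ± 0.122 (adjusted p = 1), with the same mean on both sides. Among the genes with the largest higher values were DIN11 at 6.11 ± 0.148, DIR5 at 5.50 ± 0.147, SEN1 at 4.89, BCAT-2 at 4.16 and the sucrose exporter gene SWEET12 at a 17.1-fold higher level. The wild-type −Fe means of DIN11 (3.67) and DIR5 (4.00) lay below the lower quartile of those arrays, 4.66. NRT2:1 was lower by −4.69 ± 0.144. Transcripts of photosynthesis, the markers of shoot tissue, were higher on the same arrays, as given with the lists.

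Every measured coumarin gene was lower (8 of 8, and 8 adjusted over the list alone), with a list median of −2.98 and BGLU42, a root glucosidase gene, at −3.57. Of 12 iron regulators 8 were lower, 1 was higher and 3 did not pass (10 lower and 1 higher adjusted over the list alone). The 2 probe sets of BTSL1 gave −2.49 and −1.555. General phenylpropanoid genes were lower in 13 of 15 cases and higher in 1 (13 and 1 adjusted over the list alone), with PAL2 at −1.86 and 4CL1 at −1.74. The 1 higher gene was not called without wild-type −Fe replicate 2 or either uri −Fe array, which left 0. These 3 lists passed camera (adjusted p = 3.73e-06 for regulators, 3.54e-14 for coumarins and 1.67e-09 for phenylpropanoids) and also passed with an estimated correlation (adjusted p = 0.0425, 0.0235 and 0.0239). Iron uptake genes were lower in 7 of 8 cases and higher in 1, with HMA3 at −2.39 and AHA7 at −2.18. Iron distribution genes were lower in 8 of 18 cases and higher in 3 (9 and 3 adjusted over the list alone), with OPT3 at −3.09 and NAS1 at −2.15. Both lists passed camera, and both had adjusted p = 0.111 with an estimated correlation. Of 10 iron storage genes 1, VTL1 at −0.73, was lower and 9 did not pass.

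Photosynthesis transcripts were higher in 22 of 22 cases on the arrays labelled uri −Fe (22 adjusted over the list alone, median 1.00), with GAPA at 2.09 and PSBQ2 at 1.79, and adjusted p = 0.111 with an estimated correlation. Endodermis and suberin markers were lower in 11 of 15 cases and higher in 1 (0 without wild-type −Fe replicate 1 or uri −Fe replicate 1), with the suberin genes CYP86B1 at −1.18 and FAR4 at −1.10, and adjusted p = 0.242 with an estimated correlation. Cell division markers were lower in 7 of 9 cases, with MCM2 at −0.95, and adjusted p = 0.111 with an estimated correlation. Root hair markers were lower in 5 of 9 cases (3 without uri −Fe replicate 1), with LRX1 at −1.11, and adjusted p = 0.242 with an estimated correlation. Heat shock genes were higher in 4 of 5 cases, with HSP101 at 0.86, and jasmonate genes in 6 of 7, with AOS at 0.93, each with adjusted p = 0.134 with an estimated correlation. The wild-type −Fe means of HSFA2 (4.30), HSP17.4 (4.32) and LOX4 (4.22) lay below the lower quartile of those arrays, 4.66. So did the wild-type −Fe values of JAZ8 (4.00 and 4.17), and the sizes of these differences are uncertain. The jasmonate count was 2 without wild-type −Fe replicate 1 and 3 without either uri −Fe array. Sulfate limitation genes were lower in 4 of 10 cases and higher in 1 (adjusted p = 0.0318, and adjusted p = 0.277 with an estimated correlation), a call lost without uri −Fe replicate 1 (adjusted p = 0.0796). Vascular markers were lower in 5 of 9 cases and higher in 2, with CESA7 at −0.83 (adjusted p = 0.0486, and adjusted p = 0.174 with an estimated correlation). The vascular call was lost without wild-type −Fe replicate 1 (adjusted p = 0.0597), either uri −Fe array (0.0569 and 0.0687) or either uri +Fe array (0.0587), and 3 lower members were called without uri −Fe replicate 2. The 2 higher members were 0 without either wild-type −Fe array or uri −Fe replicate 1, and 1 without uri −Fe replicate 2. The salicylate list did not pass (adjusted p = 0.707), with a median of −0.06 and a mean of 0.19.

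Under −Fe, limma called 6057 probe sets between the genotypes, of which 2784 were higher and 3273 lower in uri, with 555 and 510 differing at least 2-fold. The count was 3609 without wild-type −Fe replicate 1 and 3758 without wild-type −Fe replicate 2. With each array centred on its median, 3227 were higher and 2796 lower. Directions drawn from the label uri carry the limit that URI itself did not differ between these arrays.

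The fourth comparison asked whether uri roots differ from wild type with iron supplied. The iron-response genes gave small values that did not pass, with IRT1 at 0.16 ± 0.193 SE (2 arrays per group, adjusted p = 0.758), bHLH39 at −0.23 ± 0.117, bHLH101 at −0.11 ± 0.173, PYE at −0.40 ± 0.125, BTS at 0.02 ± 0.147, F6'H1 at 0.09 ± 0.128 and FER1 at −0.11 ± 0.122. URI was 2.03-fold lower, the largest change among iron regulators. Genes of flavonoid synthesis stood among the largest higher values, with TT5 (AT3G55120), chalcone isomerase, at 2.17 ± 0.138, TT7 at 2.03 ± 0.141 and FLS1 at 1.99 ± 0.131. The glycosyltransferase gene AT2G22590 was higher by 2.85 ± 0.290 from a wild-type mean of 4.54, below the lower quartile of those arrays (4.71), and ELIP1, a light-stress protein gene, by 2.35 ± 0.243. DGAT3 (AT1G48300) was the most reduced, at −2.42 ± 0.137, and the cell wall xylosidase gene BXL2 was lower by −2.12 ± 0.181. AT1G33055 was lower by −1.75 ± 0.335 (adjusted p = 0.0153), which was lost without wild-type +Fe replicate 1 (−1.46, adjusted p = 0.18) and with a trended and robust prior (adjusted p = 0.183).

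Sulfate limitation genes were higher in uri +Fe roots in 7 of 10 cases (8 adjusted over the list alone, median 1.06), with SDI1 at 1.64, LSU1 at 1.44 and APR3 at 1.27 (camera adjusted p = 4.31e-12, and adjusted p = 0.133 with an estimated correlation). The nicotianamine synthase genes NAS2 at 1.04 and NAS1 at 0.94 were the 2 of 18 iron distribution genes that were higher, and VTL2 at −1.07 and VTL1 at −0.85 were among 3 of 10 storage genes that were lower. Of 12 regulators 1, URI, was lower. None of 8 uptake and none of 8 coumarin genes passed, while 4CL3 at 2.24 was one of 2 higher phenylpropanoid genes of 15. The other was PAL1 at 0.52, which was not called without any 1 array other than uri +Fe replicate 1 (adjusted p from 0.0529 to 0.136). Endodermis and suberin markers were lower in 6 of 15 cases (7 lower and 2 higher adjusted over the list alone), with CASP5 at −1.24. That count was 1 without wild-type +Fe replicate 1, 2 without uri +Fe replicate 2, and 3 without wild-type +Fe replicate 2 or either wild-type −Fe array. Photosynthesis transcripts were lower in 3 of 22 cases (7 lower and 1 higher adjusted over the list alone), with 1 called without wild-type +Fe replicate 1 and 0 without wild-type +Fe replicate 2 or uri +Fe replicate 2. Vascular markers were lower in 2 of 9 cases (4 adjusted over the list alone), with SUC2 at −0.61, and 0 or 1 were called without any 1 array.

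Camera called 8 lists in this comparison, those of sulfate, regulators, distribution, storage, phenylpropanoid, endodermis, photosynthesis and vascular genes, and 0 with an estimated correlation. The regulator list holds URI, the mutated gene, which was its only called member here. Its call therefore partly restates the mutation, and the list was not tested without URI. The adjusted p with an estimated correlation was 0.133 for sulfate, phenylpropanoid and vascular genes, 0.273 for regulators, 0.292 for distribution, 0.343 for storage, and 0.439 for endodermis and photosynthesis. Leaving out wild-type +Fe replicate 1 ended the call of regulators (adjusted p = 0.105), distribution and storage (0.089 each), and left 5 lists. Without wild-type +Fe replicate 2, distribution, storage and photosynthesis were lost (adjusted p = 0.081 each), and without uri +Fe replicate 1 regulators (0.196) and storage (0.304). Without uri +Fe replicate 2, distribution (0.166) and endodermis (0.0625) were lost, and without either uri −Fe array distribution and storage (0.0591 each). With fry, which does not compare a list with other genes, endodermis and photosynthesis genes were also not called (directional adjusted p = 0.129 each). The phosphate list did not pass (adjusted p = 0.812), with a median of 0.01 and a mean of −0.03.

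With iron supplied, limma called 709 probe sets, of which 304 were higher and 405 lower in uri, with 54 and 50 differing at least 2-fold. The count was 179 without wild-type +Fe replicate 1, 415 without wild-type +Fe replicate 2, 313 without uri +Fe replicate 2, 422 without either wild-type −Fe array, and 1379 without uri +Fe replicate 1. The majority of calls under +Fe turned from lower to higher in uri without wild-type +Fe replicate 2 or without uri +Fe replicate 2. Of the 2784 probe sets higher in uri under −Fe, 86 were also higher under +Fe and 182 were lower, against 37.2 and 49.6 for independent lists. Of the 3273 lower under −Fe, 105 were also lower under +Fe and 110 were higher, against 58.3 and 43.7. Both comparisons use 1 shared estimate of spread per probe set, which alone can raise these overlaps.

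**Figure D2:**
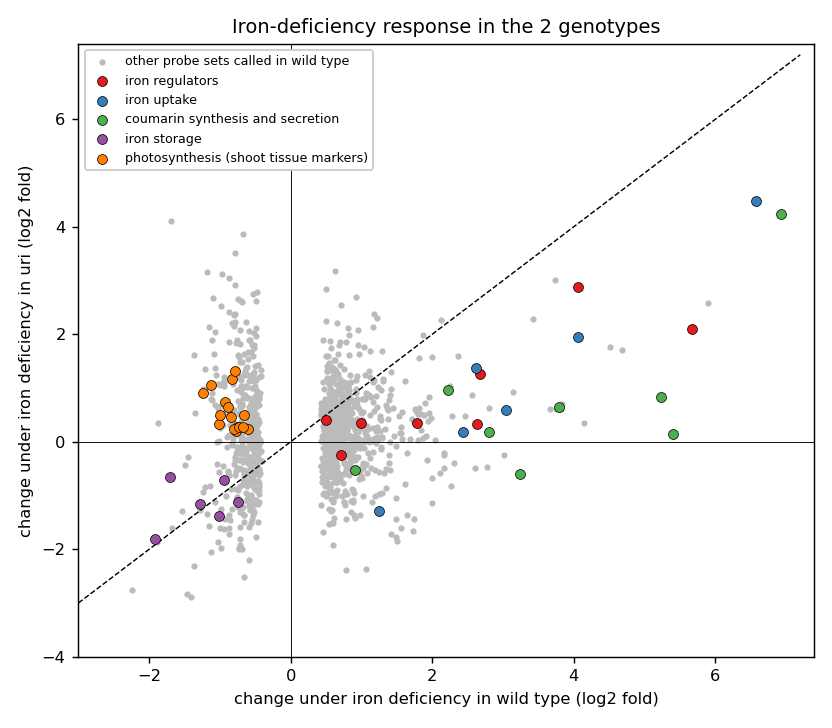
Log2 change under iron deficiency in uri (vertical axis) against that in wild type (horizontal axis) for the 1285 probe sets called in wild type, with members of 5 gene lists coloured and a dashed line of equal response. Coumarin, uptake and regulator genes that rose in wild type lie below the line, FER1 and VTL1 lie near it whereas VTL2 lies above it, and photosynthesis genes that fell in wild type lie above 0 in uri.

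The fifth comparison tested whether the iron response differed between genotypes. The response of bHLH39 was weaker in uri by a log2 difference of −3.57 ± 0.166 SE (2 arrays per group, adjusted p = 7.56e-08), that of F6'H1 by −2.61 ± 0.181, that of IRT1 by −2.09 ± 0.273, that of bHLH101 by −1.17 ± 0.245 and that of PYE by −0.95 ± 0.177. Among the most negative differences were those of MYB72 at −5.25 ± 0.228, NRT2:1 at −5.03 ± 0.204 and S8H at −4.39 ± 0.195. S8H rose in wild type and far less in uri, MYB72 rose in wild type and did not pass in uri (0.14, adjusted p = 0.559), and the NRT2:1 difference was a fall in uri of −4.79. FER1 gave a difference of 0.11 ± 0.173 with a 95% interval from −0.26 to 0.49 (adjusted p = 0.716). BTS differed by −0.66 ± 0.208 (adjusted p = 0.0415), a call lost on leaving out any 1 array except uri −Fe replicate 1, with adjusted p from 0.0623 to 0.173, and with each array centred on its median (−0.60, adjusted p = 0.0568). Among the most positive differences were those of DIR5 at 5.89 ± 0.208, SEN1 at 5.80 ± 0.206, DIN11 at 5.73 ± 0.209 and BCAT-2 at 4.54 ± 0.184. The sizes for MYB72, DIR5 and DIN11 are uncertain, because their levels outside wild type −Fe (MYB72) or uri −Fe (DIR5 and DIN11) lay near or below the lower quartile of the arrays, as did the +Fe levels of bHLH39. SEN1 fell by 1.70 in wild type and rose 17.2-fold in uri, and BGLU42 rose by 3.24 in wild type and fell by 0.60 in uri.

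Among the lists, the response in uri lay below that in wild type for all 8 coumarin genes (8 adjusted over the list alone) and for 12 of 15 phenylpropanoid genes (14 adjusted over the list alone), with PAL2 at −2.28 and PAL1 at −2.24. Such a difference is not always a weaker response, since 4CL3 rose in wild type and fell by 1.85 in uri, and PAL1 rose by 1.28 and fell by 0.95. Both lists passed camera and also passed with an estimated correlation (adjusted p = 0.0187 each). Iron uptake gave 7 lower and 1 higher of 8, with AHA7 at −2.54 and MTP3 at −2.11. Regulators gave 7 lower and 2 higher of 12, with the 2 probe sets of BTSL1 at −2.30 and −1.53. The 2 higher regulators include URI, the mutated gene itself, at 0.97. Iron distribution gave 7 lower and 1 higher of 18, with OPT3 at −3.15 and NAS1 at −3.09. The adjusted p with an estimated correlation was 0.0994 for uptake and 0.0939 for regulators and distribution. Of 10 storage genes 1 passed, VTL2 at 1.05, and the list did not pass (camera adjusted p = 0.247). Photosynthesis genes differed upwards in 20 of 22 cases (22 adjusted over the list alone, median 1.24), with PSBQ2 at 2.19 and PSAN at 2.15. Sulfate limitation genes differed downwards in 8 of 10 cases, with SDI1 at −2.45 and APR1 at −2.03, and cell division markers in 6 of 9, with PCNA1 at −1.22. These 3 lists passed camera, each with adjusted p = 0.0994 with an estimated correlation.

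Root hair markers differed downwards in 6 of 9 cases, with LRX1 at −1.33, but 2 were called without wild-type −Fe replicate 2 or wild-type +Fe replicate 1 and 3 without uri −Fe replicate 1. Jasmonate genes gave 2 of 7 higher (1 without uri −Fe replicate 1, and 0 without any 1 of the 4 wild-type arrays or uri +Fe replicate 2). Heat shock genes gave 3 of 5 higher (1 without wild-type −Fe replicate 2), and these 3 lists had adjusted p = 0.216 with an estimated correlation. The jasmonate list was lost without wild-type −Fe replicate 1 (adjusted p = 0.0633) or uri +Fe replicate 2 (0.0513). The heat shock list was lost without wild-type −Fe replicate 2 (0.0594), wild-type +Fe replicate 2 (0.06) or uri +Fe replicate 2 (0.0731). Copper genes gave 1 lower of 8 (2 without uri −Fe replicate 1), COPT2 at −3.24, and did not pass (camera adjusted p = 0.0639). Zinc genes gave 4 higher and 2 lower of 11, with HMA4 at 1.29, and did not pass (adjusted p = 0.464). Of the zinc genes 2 were higher without wild-type −Fe replicate 2, and 1 was lower without either wild-type −Fe array, uri −Fe replicate 2 or wild-type +Fe replicate 2. For salicylate genes, which did not pass (adjusted p = 0.906), the median of −0.08 and mean of 0.12 differed in sign.

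The interaction called 4637 probe sets, 2183 upwards and 2454 downwards, with 782 and 693 of at least 2-fold. The count was 2905 without wild-type −Fe replicate 1 and 2849 without wild-type −Fe replicate 2, and with each array centred on its median 2439 differed upwards and 2034 downwards. Among the 798 probe sets that rose in wild type, 459 (57.5%) responded less or the opposite way in uri and 51 responded more, when adjusted over those probe sets alone. Of the 798, 314 (39.3%) were also called higher in uri and 165 were called lower, against 120.5 and 144 for independent lists. Among the 487 that fell, 290 (59.5%) responded less or the opposite way in uri and 54 more. Of these, 170 (34.9%) were also called lower in uri and 173 were called higher, against 87.7 and 73.5. The genotypes' responses share 1 estimate of spread per probe set, which alone can raise overlaps in either direction. An excess over independent lists therefore does not by itself show a shared response. The median change of the 192 probe sets raised at least 2-fold was 1.39 in wild type and 0.29 in uri. Selection on the wild-type arrays inflates the wild-type values. The reverse was also taken, which selects on the uri arrays and inflates the uri values in the same way. Of 3434 probe sets raised in uri, 2383 (69.4%) responded less or the opposite way in wild type, and of 4094 lowered in uri, 2684 (65.6%) did so. Across probe sets, which are not independent replicates, the responses of the genotypes correlated with r = 0.111.

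**Figure D3:**
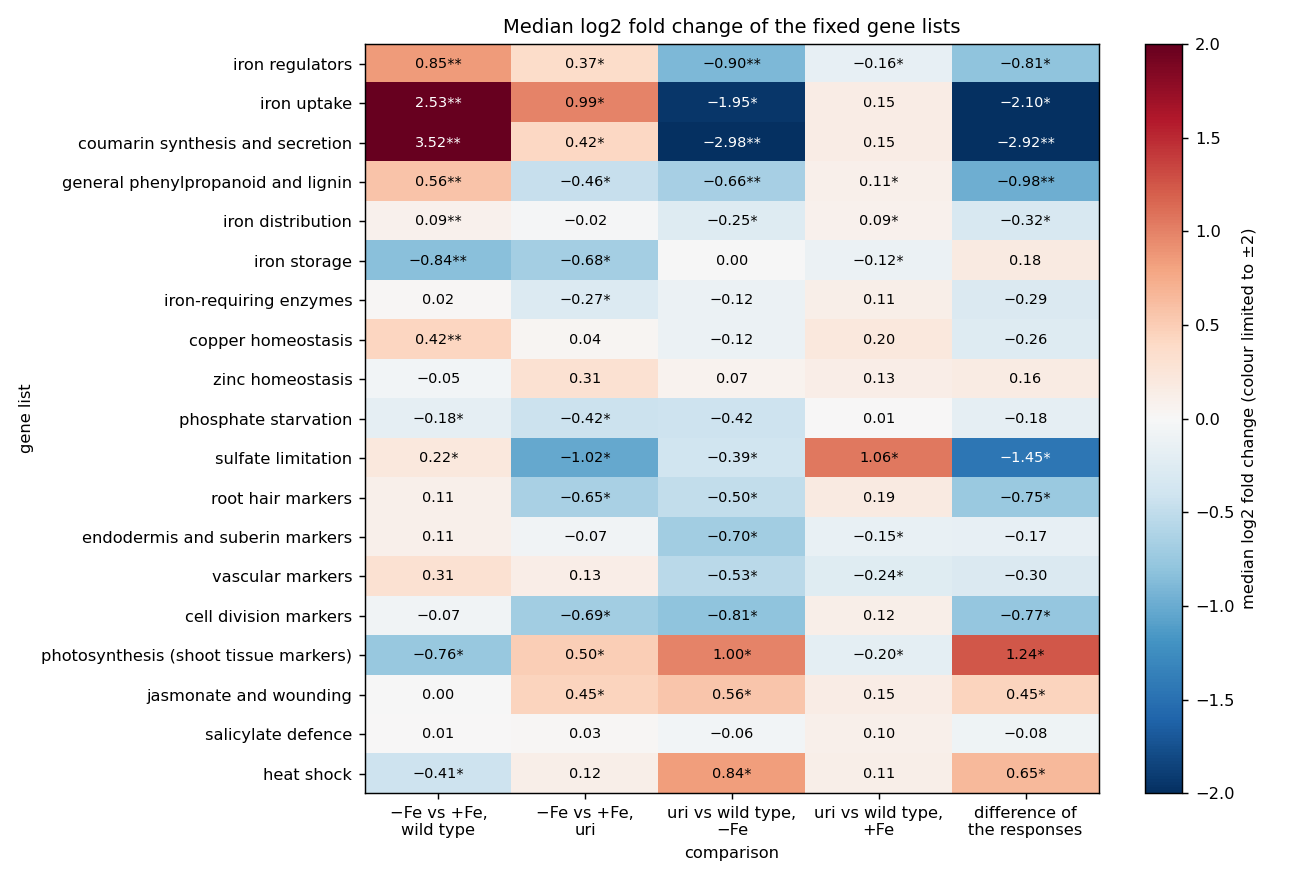
Median log2 fold change of each of the 19 gene lists (vertical axis) in each of the 5 comparisons (horizontal axis), with 1 star where camera passed with the preset correlation and a further star where it also passed with an estimated correlation. Coumarin genes run from 3.52 in wild type to 0.42 in uri, and photosynthesis genes from −0.76 to 0.50.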

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

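Of the explanations weighed in this part, those for the dark-induced programme and the first for the photosynthesis transcripts were written down before the result of their test was seen. Those for the URI transcript, and the second for the photosynthesis transcripts, were written after. The results in the next paragraph were picked out because the iron responses of wild type and uri differed by the test of the difference itself.

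The iron response differed between genotypes for 4637 probe sets, and 338 probe sets were called in opposite directions in wild type and uri. The difference was called for all 338, which 2 opposite calls on 1 shared spread make nearly certain, so it adds no support. Among the fixed lists, 11 differed with the preset correlation and 2 with an estimated correlation. By gene, the difference between the uri and the wild-type response was 0.97 for URI, −2.09 for IRT1, −3.57 for bHLH39, −1.17 for bHLH101, −0.95 for PYE, −0.66 for BTS and −2.61 for F6'H1. Iron supply and array run share the arrays here, but a run effect common to both genotypes cancels in these differences.

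The first pattern weighed was the sugar-starvation and dark-induced programme in the arrays labelled uri −Fe, to which DIN11, SEN1 and BCAT-2 belong. Harvest at another time of day would have moved morning and evening clock genes apart, and this was left undecided, since the morning minus the evening median differed by −0.25 (95% interval from −0.55 to 0.11) over 3 morning genes, 1 of them higher (0 without wild-type −Fe replicate 2 or uri −Fe replicate 1), and 5 evening genes, 2 of them higher (1 without wild-type −Fe replicate 2 or uri −Fe replicate 2) and 1 lower (0 without any 1 of the 4 −Fe arrays). Poorer RNA or labelling would have raised the difference between the 3' and 5' control probes. The farther uri −Fe array lay 0.0956 outside the range of the other 6 arrays (0.579 to 0.911), on the side of the smaller difference, which argues against it. Of 17 starvation genes not seen beforehand 15 were higher, with a median of 1.34 (95% interval from 1.22 to 1.57). Over all 22746 probe sets 2784 were higher. The list was written after the first genes were seen and was read on the same arrays. Most of its other members thus moved with those genes, but this is not separate support for any cause. What switched these genes on is not shown. A carbon shortage, plate and growth differences stay open. The interval, like that of the clock genes, redraws each gene independently from its SE. It leaves out error that genes share and does not measure the spread between plants.

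The second pattern was the URI transcript, lower in uri +Fe but not in uri −Fe, where exchanged labels between the −Fe arrays would have put URI higher on the arrays labelled uri, by about the 1.02 that separates the genotypes under +Fe. The upper 95% bound of the difference was 0.20, so an exchange would not account for the pattern, but equal levels look alike with labels kept or exchanged and leave the labels themselves unchecked. Wild-type roots grown alike would have correlated with wild type like replicates, but the highest correlation was 0.977, against 0.994 for the lowest replicate pair. For wild-type roots that grew otherwise, 483 probe sets were called between genotypes under both iron supplies, against 189 for independent lists. Of them 39.5% went the same way (binomial 95% interval over probe sets, which are not independent, from 35.2% to 44.1%). Both comparisons share 1 estimate of spread per probe set, which alone can raise the overlap. The count therefore cannot decide, and this explanation stays open. A run difference common to both genotypes would have raised URI in wild type as in uri (0.83). The wild-type change was −0.13 (95% interval from −0.39 to 0.12), so such a difference alone would not account for the pattern. This reading and that of exchanged labels use the same URI values that define the pattern, so neither is separate evidence. No biological explanation was tested.

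The third pattern was the higher photosynthesis transcripts in the arrays labelled uri −Fe. Shoot tissue carried into the samples could have raised them. The rise of a gene would then also depend on its own level in roots, so lists need not rise equally. The 95% interval given next resamples genes, so it measures the spread over genes and not over plants. The prediction written beforehand was a rise of about the same size in other leaf-abundant transcripts. Their median minus that of the photosynthesis list was −0.49 (95% interval from −1.37 to 0.30, medians 0.50 over 10 genes and 1.00 over 22), and 5 of the 10 were higher and 2 lower (1 lower without wild-type −Fe replicate 2 or uri −Fe replicate 2), so shoot tissue could not be told apart from a root response. A response of photosynthesis genes that follows genotype and iron supply was left undecided as well. It was read from the list's interaction (camera adjusted p = 9.59e-19 with the preset and 0.0994 with an estimated correlation). Shoot tissue carried only into the uri −Fe samples would give the same interaction, so this test cannot separate the explanations at either setting.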

How the results depend on the processing

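All alternatives were fixed before the data were examined except the split selection, which was added after the result was seen. With an adjusted p under 0.01, 616 probe sets remained for wild type, 3920 for the genotypes under −Fe, 248 under +Fe and 2492 for the interaction. A minimum of 2-fold left 248 in wild type, 1202 in uri, 1065 under −Fe, 104 under +Fe and 1475 for the interaction. Under +Fe the trended and robust prior gave 1113 and only the arrays compared gave 295, against 709. With an estimated correlation the lists that passed numbered 7, 0, 3, 0 and 2 in the order of the comparisons, against 11, 12, 13, 8 and 11. That test also rests on fewer degrees of freedom, so these losses do not measure correlation alone. Leaving out each array in turn gave 435 to 1729 in wild type, 5404 to 7540 in uri, 3609 to 6833 under −Fe, 179 to 1379 under +Fe and 2849 to 4937 for the interaction. It gave 5 to 8 lists under +Fe, and shares of the wild-type response that differed in uri of 51.1% to 73.8% for raised and 53.4% to 67.9% for lowered probe sets. Probe sets chosen on one replicate number and measured on the other gave a uri median of −8.90% and −14.3% of the wild-type median for lowered probe sets, against −25.6%, and 23.7% and 19.9% for raised ones, against 20.9%. With the replicate block the counts were 1164, 7282, 5830, 610 and 4376, and a call lost under it is not a weaker effect. Of the 8 lists called under +Fe, distribution (adjusted p = 0.0561) and storage (0.0671) were lost under it. Residuals of arrays with the same number correlated between groups at −0.22 to 0.16, so the numbers carry little shared signal. Quantile normalization gave 1390, 7632, 6191, 792 and 4715. Of 363 calls of named genes, 64 were lost under some alternative, all 64 of them on leaving out an array, 41 at the stricter adjusted p and 4 under the block. Directions reversed for 0 of the 363 calls. The minimum of 2-fold and the fit of only the arrays compared were not applied to the named genes, so the losses leave these 2 alternatives out.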

Other observations

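The gene lists in this part were written after the main table was seen, and their counts use only members not seen beforehand unless stated. Starvation and dark-induced genes, which roots switch on when sugar runs short, rose in uri under −Fe in 17 of 17 cases, with a median of 1.39. In wild type 10 of the 17 fell, with a median of −0.51, but 4 without wild-type −Fe replicate 1, 3 without wild-type −Fe replicate 2, 6 without wild-type +Fe replicate 1 and 5 without wild-type +Fe replicate 2 did so. Between the genotypes under −Fe 15 of the 17 were higher in uri, including the asparagine synthetase gene ASN1 at 2.17 ± 0.121 SE (2 arrays per group, adjusted p = 9.85e-08), BGLU30 at 2.93, the glutamate dehydrogenase gene GDH2 at 2.17 and the leucine breakdown genes IVD at 2.28 and MCCA at 2.04. ATG8E at 0.13 and D2HGDH at 0.07 did not pass. Under +Fe the direction was the other way, with 8 lower and 1 higher in uri and a median of −0.53, and the interaction was called upwards for 15 of 17. The 1 higher gene was not called without either wild-type −Fe array, wild-type +Fe replicate 1 or either uri +Fe array, which left 0.

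Flavonoid synthesis genes, which were prominent among the largest values in uri +Fe roots, were higher there in 4 of 8 cases not seen beforehand, with F3H at 1.21, MYB12 at 1.15, UGT78D2 at 1.43 and CHS at 0.56. The median of these 8 was 0.31. Under iron deficiency 3 of the 8 rose in wild type and 3 fell in uri, and the interaction was called downwards for 4, with a median of −0.34. With the 4 members seen beforehand, which were chosen for their large values, the +Fe median was 1.18 and the interaction median −1.46. Nitrate response genes, measured because the transporter gene NRT2:1 fell so far in uri, were lower under −Fe in 4 of 8 cases, with G6PD3 at −1.32 ± 0.118 and the dual-affinity transporter gene NRT1.1 at −0.82. Of the 8, 2 were higher, but 0 without any 1 of the 4 −Fe arrays, and 2 were lower without uri −Fe replicate 1. The iron response differed by −2.14 for G6PD3 and by −1.39 for NRT1.1. The cause was not tested.

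On the leaf-abundant list, GOX1 at 1.33, FBA2 at 1.56 and LHCB1.1 at 0.94 were higher in the arrays labelled uri −Fe, whereas GLDP1 at −1.06 was lower and CA1 at −0.11 did not pass. A principal component analysis of all probe sets placed the uri −Fe arrays apart from the other 6 on the first component, which held 53.8% of the variance. The second component, with 21.3%, set wild type −Fe apart.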
